A study of Homo sapiens with 8 samples.

How the data were processed

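RNA was measured in 8 libraries from 2 human colorectal cancer cell lines, HCT116 and SW620, each treated for 24 hours with 5-fluorouracil (5-FU) or with a preparation that the labels call AFZC, with 2 libraries in each of the 4 groups. Per the labels, polyadenylated RNA was selected with oligo(dT) beads, libraries did not keep the strand, and sequencing was on an Illumina instrument. The authors deposited raw counts per gene symbol for all 8 libraries as a single file with the layout of featureCounts. The submitters' processing notes name FastQC, Trimmomatic, cutadapt, HISAT2, STAR, featureCounts, DESeq2 and edgeR and the genome build GRCh38. Which aligner made the counts, how reads with several alignments were treated and whether mates were counted singly are not given in the sources used here.

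The deposited table held 57169 rows. Symbols were compared with GENCODE release 29 on GRCh38: 57142 rows had a symbol of that release, 56998 of them at the same chromosome, start and end, and 27 symbols that had been turned into dates were restored by position. The exons of 109 rows lay on more than 1 chromosome or scaffold. Every column of values matched 1 library. In all 8 libraries, genes with 2 counts were 1.68 to 1.84 times as many as genes with 1 count, the pattern left by counting both mates of a fragment. Counting intervals and floors, which treat each count as independent, are therefore too narrow, and they cover counting error only.

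Total counts ran from 31991561 to 40590291 per library. A gene without counts in a group is given as a bound against 3 counts over the group, and genes with few counts as a ratio with its 95% exact binomial interval. Both pool the libraries of a group, so a bound holds for the pooled counts and not for each library. Fold changes fitted by edgeR for such genes depend on the prior count and are not bounds.

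The analysis used edgeR 4.0.16 in R 4.3.3, the data.table package (1.17.8) for input, and limma 3.58.1 for gene lists. Counts passed filterByExpr with a minimum count of 10, which left 21378 genes, and were scaled with TMM factors. One quasi-likelihood model with 4 group means was fitted to all 8 libraries with robust dispersion, which left 4 residual degrees of freedom. Contrasts gave AFZC against 5-FU in HCT116, AFZC against 5-FU in SW620, the difference of these 2 effects, and SW620 against HCT116 under 5-FU. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and the standard error of a log2 fold change was taken as its size over the square root of F. Levels are CPM (counts divided by the library total, in units of 1e6) scaled with TMM factors, as mean ± SD. The common dispersion corresponded to a coefficient of variation of 19.9%. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The 2 libraries of each group differed by more than counting noise (chi-square per degree of freedom of 20.9 to 51.5), so none was a copy of another.

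Before the data were examined, 35 gene lists were fixed and tested with camera at a preset correlation of 0.01, adjusted over the lists within each contrast. Camera with an estimated correlation and fry were alternatives. Members are counted with adjustment over all genes tested and adjusted over the list alone. Named genes followed a rule fixed at the same time: per treatment comparison the 6 largest rises and 6 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1, no overlap between the libraries of the 2 groups and no clone or antisense name; from each list the 2 called members with the largest change; 8 genes in both lines whatever their result (CDKN1A, MDM2, TYMS, GPX4, SLC7A11, HMOX1, ACSL4 and MT2A); and the 5 largest in each direction for the other contrasts. Members are named for 20 lists, the last 4 of which were added after the results were seen, 14 are counted with some of the members that this rule picks, which were not tried in other settings, and 1 list and 1 named gene are not reported here, though counts of calls and of lists called under each setting include them. LYZ, COL1A1, LUM and CBSL were named outside the rule, after their values were seen.

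The steps were tested on negative binomial counts simulated with 1 mean per gene and line and the fitted dispersions and library sizes, with 200 changed genes among 20682 tested in the simulated HCT116 comparison. EdgeR recovered 60% of genes changed 2-fold and 87% of those changed 4-fold, with 7.36% false calls. DESeq2 recovered 68.4% and 91.6%, with 12.6% false calls. The 200 genes were changed in HCT116 alone, equally in both directions, with 1 dispersion per gene for all groups. In the data 9.61% and 18.6% of genes were called in HCT116 and SW620. There, AFZC libraries differed more (chi-square per degree of freedom of 51.47 and 47.79) than 5-FU libraries (23.55 and 20.91). The simulated rates therefore need not hold for the data. Camera called a simulated list of 30 genes shifted 1.5-fold and 0 of 34 unshifted lists. The simulated genes varied independently, so this does not test camera on lists whose members vary together. In the data the estimated correlation was 0.882 for cytosolic ribosomal proteins in the HCT116 comparison.

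Alternatives fixed beforehand were median-of-ratios factors, library sizes only, no low-count filter, a minimum count of 50, DESeq2 1.42.0, fits on fewer libraries, the replicate number as a block, and leaving out each library in turn. Offsets that take out the trend of each library over mean abundance (loess, span 0.3), and gene lists with library sizes only, were added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.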

Results

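The series compared a nanodrug with free 5-FU, the thymidylate synthase inhibitor used against colorectal cancer, in 2 colorectal carcinoma lines. Per the series title, the nanodrug is an aptamer-modified metal-organic framework that carries 5-FU and is studied for peroxidative cell death. SW620 was grown from a lymph node metastasis. Each line was treated at the IC50 dose of each agent, and untreated cells were not analysed here, so every change is relative to 5-FU. Each of the 4 groups had 2 libraries. Totals were 33764058 to 36518758 counts in HCT116 and 31991561 to 40590291 in SW620. Counts were found for 26500 and 27443 genes in the HCT116 5-FU libraries and for 28340 and 27616 under AFZC, and for 24744 and 24427 in the SW620 5-FU libraries and 27591 and 26597 under AFZC. Adjusted p-values of single genes are from edgeR's quasi-likelihood test and those of gene lists from camera.

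The first comparison asked what AFZC changed relative to 5-FU in HCT116. CDKN1A, MDM2 and FAS were among the genes that rose. CDKN1A, the p21 inhibitor of cyclin-dependent kinases (chromosome 6, 36676460 to 36687339, GRCh38), rose from 182 ± 9.87 to 1832 ± 281 CPM (SD, n = 2), a log2 fold change of 3.33 ± 0.224 (SE, adjusted p = 7.94e-06). TP53I3, a quinone oxidoreductase, rose from 10.1 ± 2.12 to 141 ± 14.3 CPM (log2 fold change 3.80 ± 0.208, adjusted p = 3.2e-06). MDM2, a ubiquitin ligase, rose from 98.4 ± 9.27 to 660 ± 338 CPM (log2 fold change 2.75 ± 0.299, adjusted p = 0.000519). Among apoptosis regulators, 10 of 27 rose and 0 fell (13 and 1 adjusted over the list alone, adjusted p = 1.11e-07, and adjusted p = 0.854 with an estimated correlation). Death receptors led that list, with log2 fold changes of 2.66 ± 0.227 for FAS (adjusted p = 4.17e-05) and 1.53 ± 0.196 for TNFRSF10A (adjusted p = 0.000713). The apoptosis members higher were 6, 5 and 6 without replicate 1 of 5-FU, replicate 2 of 5-FU and replicate 1 of AFZC.

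In all, 1254 genes were higher and 800 lower under AFZC in HCT116, of 21378 tested, and 780 and 345 of these changed at least 2-fold. GGT6, HRNR and KRT17 were among the largest rises. GGT6, a gamma-glutamyltransferase family member (chromosome 17, 4556927 to 4560818), had 0 counts under 5-FU and 852 under AFZC, at least 271-fold higher by pooled counts. Replicates 1 and 2 of AFZC held 628 and 224 of these. LCE1F and HRNR, proteins of the cornified envelope, were 235-fold (64.7 to 1950) and 185-fold (51 to 1540) higher by their counts, and KRT17, a keratin, was 163-fold higher (69.4 to 502). CHRNA6, a nicotinic receptor subunit, was 260-fold higher (71.5 to 2150) and SYT8, a synaptotagmin, 141-fold higher (54.9 to 520). The call of LCE1F was lost without replicate 1 or 2 of 5-FU (adjusted p up to 0.0726) and with DESeq2 (adjusted p = 0.286). The largest falls were LRP1B, SPARC, TMEM132B, RPL22L1, CUBN and TNFSF18, with log2 fold changes of -3.38, -2.86, -2.73, -2.32, -2.30 and -2.30. Of these, RPL22L1, a ribosomal protein paralog, was the most abundant, falling from 160 ± 25.7 to 32.2 ± 10.1 CPM (adjusted p = 0.000122). LRP1B and CUBN lost their calls without replicate 2 of 5-FU (adjusted p = 0.0853 and 0.0578), and TNFSF18 without either 5-FU library (up to 0.116). The intestinal differentiation list had 6 of 24 members higher and 0 lower (7 and 0 adjusted over the list alone, adjusted p = 0.000148, and adjusted p = 0.886 with an estimated correlation), led by the mucins MUC2, 77.7-fold higher by counts (30 to 287), and MUC13, 32.2-fold (12.3 to 120; log2 fold change 4.92, or 8.99 without replicate 1 of 5-FU, which leaves 0 counts there).

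Messenger RNAs of cytosolic ribosomal proteins were lower in HCT116 under AFZC: 31 of 38 fell and 0 rose (38 adjusted over the list alone), with a median log2 fold change of -0.86 (adjusted p = 1.33e-31, and adjusted p = 0.854 with an estimated correlation). RPL10A fell from 803 ± 130 to 199 ± 57.2 CPM and RPL3 from 3495 ± 473 to 905 ± 124 CPM, by 2.02 and 1.95 on the log2 scale (adjusted p = 0.000887 and 0.0018). The list took 5.56% and 4.49% of counts in the 5-FU libraries and 2.46% and 2.96% under AFZC. The number of members lower was 3 without replicate 1 of 5-FU and 6 without replicate 1 of AFZC, with the list median between -1.04 and -0.68 over the left-out libraries.

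Replication genes as a group did not pass the test in HCT116, with 3 of 33 higher and 2 lower (the same counts adjusted over the list alone) and a median log2 fold change of 0.04 (adjusted p = 0.8). PCNA, the replication clamp, rose from 163 ± 21.2 to 385 ± 58.1 CPM (log2 fold change 1.24 ± 0.166, adjusted p = 0.000884), and E2F8, a repressor of the E2F family, rose by 1.38 ± 0.282 (adjusted p = 0.00974). Of 24 genes of pyrimidine metabolism, 4 rose and 1 fell, also over the list alone (adjusted p = 0.197). RRM2B, a ribonucleotide reductase subunit, rose by 1.48 ± 0.156 (adjusted p = 0.000178) and RRM2, its S-phase counterpart, by 1.06 ± 0.23 (adjusted p = 0.0139). TYMS, the enzyme that 5-FU inhibits, was at 16.9 ± 0.636 and 25.3 ± 7.43 CPM (adjusted p = 0.169). In the mitosis list 2 of 32 were higher, PTTG1 and UBE2C (log2 fold changes 0.82 and 0.72), and 0 lower, also over the list alone (adjusted p = 0.00808, and adjusted p = 0.886 with an estimated correlation). That list's call was lost without replicate 2 of AFZC (adjusted p = 0.417), with a median of 0.00279 there and 0.79 without replicate 1. Over left-out libraries and other settings its members higher were 0 to 10 and lower 0 to 3, against 1 to 4 and 0 to 5 for replication, 1 to 5 and 0 to 1 for pyrimidine metabolism and 0 to 3 and 0 for recombination. Of 19 homologous recombination and Fanconi genes, RAD51C was higher (log2 fold change 1.18) and 0 were lower (2 and 0 over the list alone, adjusted p = 0.197). Calls of E2F8, RRM2 and RAD51C were lost without 1 library, with the highest p without replicate 1 of 5-FU (adjusted p = 0.152, 0.139 and 0.064), and those of PTTG1 and UBE2C likewise without replicate 2 (adjusted p = 0.0954 and 0.147). Without replicate 2 of AFZC the value of UBE2C was 0.44.

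Genes of lipid peroxidation and iron moved little as groups in HCT116. Among ferroptosis drivers 3 of 22 rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.197), and among suppressors 2 of 23 rose and 1 fell, also over the list alone (adjusted p = 0.749). Over left-out libraries and other settings 0 to 6 drivers and 2 to 4 suppressors were higher. PROM2, a prominin tied to iron export, rose from 12.1 ± 1.89 to 65.2 ± 5.36 CPM (adjusted p = 0.000118) and AIFM2, the coenzyme Q reductase FSP1, from 29.6 ± 0.394 to 60.2 ± 3.18 CPM (adjusted p = 0.00117). ALOXE3, a lipoxygenase, rose by 1.99 ± 0.425 on the log2 scale and SAT1, the spermidine acetyltransferase, fell by 1.68 ± 0.43 (adjusted p = 0.0122 and 0.0402). GPX4, the phospholipid hydroperoxide reductase, was at 203 ± 30.2 and 173 ± 25.1 CPM (adjusted p = 0.446), ACSL4 at 116 ± 4.36 and 106 ± 10.7 CPM (adjusted p = 0.726) and SLC7A11, the cystine transporter, at 35.6 ± 4.59 and 14.9 ± 5.81 CPM (adjusted p = 0.128). HMOX1, heme oxygenase 1, rose from 14.8 ± 1.12 to 31.8 ± 6.06 CPM (log2 fold change 1.10 ± 0.244, adjusted p = 0.0142). The NRF2 list had 2 of 28 members higher and 5 lower (3 and 5 over the list alone, adjusted p = 0.481), and 1 to 3 and 3 to 6 over those settings. The aldo-keto reductase AKR1B10 was 73-fold higher by counts (39.5 to 153; log2 fold change 6.14, or 11.49 without replicate 1 of 5-FU, which leaves 0 counts there), with its call lost in DESeq2 (adjusted p = 0.185), and AKR1C1 fell by 2.25 on the log2 scale. Calls were lost without 1 library, with the highest p without replicate 1 of 5-FU for ALOXE3 and SAT1 (adjusted p = 0.128 and 0.208) and without replicate 2 for HMOX1 (adjusted p = 0.133). That of SAT1 was also lost without the low-count filter and with the abundance trend taken out (adjusted p = 0.264 and 0.109). SLC30A1, the zinc exporter, was the only called gene of 10 in the metallothionein and zinc list, also over the list alone (log2 fold change 1.32 ± 0.196, adjusted p = 0.00166, list adjusted p = 0.491). Its adjusted p was 0.0508 without replicate 1 of 5-FU. MT2A, a metallothionein, was at 342 ± 33.2 and 560 ± 166 CPM (adjusted p = 0.422).

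Other lists had few called members in HCT116. For NF-kB and inflammatory cytokines 2 of 22 rose, CSF2 and IL1A, and 0 fell (6 and 0 over the list alone, adjusted p = 0.00582, and adjusted p = 0.886 with an estimated correlation). By counts CSF2 was 38.6-fold (10.3 to 324) and IL1A 14.7-fold (7.53 to 32.9) higher. The log2 fold change of CSF2 was 5.09, but 3.38 without replicate 1 of AFZC and 8.23 without replicate 2 of 5-FU, which leaves 0 counts there. Interferon-stimulated genes had 3 of 26 higher and 1 lower (7 and 1 over the list alone, adjusted p = 0.0787), with log2 fold changes of 2.17 for OAS1 and -1.54 for BST2. The integrated stress response had 3 of 29 higher and 1 lower (5 and 1 over the list alone, adjusted p = 0.211), among them ATF3 and NUPR1 (log2 fold changes 2.97, or 1.65 without replicate 1 of AFZC, and 2.88). Immediate early and AP-1 genes had 2 of 29 higher and 4 lower (2 and 5 over the list alone, adjusted p = 0.8). FOSL1 rose by 1.48 ± 0.177 (adjusted p = 0.000433). Over the left-out libraries 1 to 12 of the 29 were higher, 12 without replicate 2 of AFZC, 1 was lower without replicate 1 of 5-FU, and the median ran from -0.32 to 0.33. WNT target and stem cell genes had 4 of 20 higher and 0 lower (4 and 3 over the list alone, adjusted p = 0.535), led by DKK1 and EPHB3 (log2 fold changes 2.16 and 1.22). In cholesterol biosynthesis TM7SF2 fell, 1 of 24 (also over the list alone, log2 fold change -0.81, list adjusted p = 0.361), and among 13 mitochondrially encoded mRNAs MT-ND1 rose (also over the list alone, log2 fold change 0.69, list adjusted p = 0.197). Histone and glycolysis lists had 0 called members of 12 and 19, also over the list alone (adjusted p = 0.544 and 0.535). Without 1 library the calls of CSF2, IL1A, OAS1, BST2, ATF3, NUPR1, EPHB3 and TM7SF2 (replicate 1 of 5-FU), MT-ND1 (replicate 2 of 5-FU) and DKK1 (replicate 1 of AFZC) were lost, with the highest adjusted p at 0.152, 0.14, 0.126, 0.215, 0.238, 0.157, 0.0834, 0.157, 0.19 and 0.199 in that order. The NF-kB list lost its call without replicate 2 of 5-FU or 1 of AFZC (adjusted p = 0.0512 and 0.255), and ATF3 and DKK1 lost theirs without the low-count filter (0.19 and 0.176), and ATF3 in a fit of HCT116 alone (0.2). Over left-out libraries and other settings members higher were 0 to 11 for NF-kB, 0 to 7 for interferon-stimulated genes, 1 to 8 for the integrated stress response (0 to 3 lower), 0 to 4 for WNT genes (0 to 3 lower), 0 to 3 for mitochondrially encoded mRNAs and 0 to 2 for glycolysis (0 to 2 lower), and 0 to 2 were lower for cholesterol biosynthesis. Across all genes, 216 were higher and 89 lower without replicate 1 of 5-FU in HCT116, 383 and 242 without replicate 2, and 509 and 269 without replicate 1 of AFZC, while 1215 and 1214 were lower without replicate 1 or 2 of SW620 AFZC.

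The same comparison in SW620 asked what AFZC changed in the line from a metastasis. Replication genes rose as a body: all 33 measured members of the E2F and DNA replication list were higher, also adjusted over the list alone, with a median log2 fold change of 2.26 (adjusted p = 3.16e-78, and adjusted p = 0.0125 with an estimated correlation). E2F8 (chromosome 11, 19224063 to 19241620) rose from 1.76 ± 0.0483 to 25.6 ± 6.8 CPM (log2 fold change 3.87 ± 0.323, adjusted p = 1.05e-05) and CCNE2, cyclin E2, from 0.942 ± 0.178 to 7.34 ± 2.05 CPM (2.96 ± 0.352, adjusted p = 0.000145). Homologous recombination and Fanconi genes followed, with 17 of 19 higher and 0 lower (18 and 0 over the list alone, median log2 fold change 1.86, adjusted p = 1.94e-32, and adjusted p = 0.0396 with an estimated correlation). RAD54L and EME1 were among them (log2 fold changes 2.77 ± 0.194 and 2.68 ± 0.232). Of 32 mitosis genes 25 rose and 0 fell (30 and 0 over the list alone, median 1.53, adjusted p = 3.98e-27, and adjusted p = 0.265 with an estimated correlation). MKI67, the proliferation antigen, rose from 111 ± 25.1 to 609 ± 205 CPM and AURKB, aurora kinase B, from 19.6 ± 3.91 to 101 ± 15.2 CPM.

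Pyrimidine metabolism rose in SW620 in 11 of 24 members and fell in 2 (12 and 2 over the list alone, median log2 fold change 0.46, adjusted p = 6.59e-08, and adjusted p = 0.0959 with an estimated correlation). That median was 0.73 without replicate 2 of AFZC and 0.84 with library sizes only, and 0 to 2 members were lower over left-out libraries and other settings. TYMS (chromosome 18, 657604 to 673578) rose from 2.39 ± 0.608 to 14.8 ± 2.15 CPM (log2 fold change 2.63 ± 0.282, adjusted p = 6.7e-05) and RRM2 from 10.3 ± 4.66 to 63.4 ± 0.00204 CPM (2.63 ± 0.248, adjusted p = 3.6e-05). In contrast to these polyadenylated cell cycle transcripts, counts of replication-dependent histone genes, whose main transcripts lack a poly(A) tail, fell in 7 of 12 and rose in 0 (8 and 0 over the list alone, median -1.92, adjusted p = 2.07e-08, and adjusted p = 0.0396 with an estimated correlation). HIST2H2BE fell from 7.02 ± 1.65 to 0.938 ± 0.291 CPM (adjusted p = 0.000519), HIST1H2AC from 12.5 ± 0.281 to 2.2 ± 0.153 CPM (adjusted p = 0.000212). HIST1H2BG had 100 counts under 5-FU and 14 under AFZC (log2 fold change -3.01, adjusted p = 0.0135, and 0.0834 without replicate 2 of 5-FU).

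In SW620 BBC3 fell and DDB2 rose. BBC3, an inducer of apoptosis, fell from 80.4 ± 21.6 to 29 ± 1.3 CPM (adjusted p = 0.000375) and DDB2, a DNA damage binding protein, rose from 24 ± 1.37 to 61.6 ± 12 CPM (adjusted p = 0.000217). CDKN1A rose from 85.6 ± 20.3 to 140 ± 24.1 CPM (log2 fold change 0.71 ± 0.207, or 1.10 with library sizes only, adjusted p = 0.0302, and 0.247 without replicate 1 of 5-FU), and MDM2 was at 38.7 ± 4 and 47 ± 5.27 CPM (adjusted p = 0.544). Apoptosis regulators split, with 5 of 27 higher and 5 lower (6 and 6 over the list alone, adjusted p = 0.869), with a median of 0.12 although camera gave a downward direction. Of these regulators 2 to 12 were higher and 1 to 6 lower over left-out libraries and other settings. CASP10 rose by 3.41 ± 0.364 and BIRC3, an inhibitor of apoptosis, by 2.25 ± 0.488 (adjusted p = 6.6e-05 and 0.0171, the latter 0.15 without replicate 1 of 5-FU and 0.0781 without the low-count filter).

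Immune signalling genes rose in SW620. For NF-kB and inflammatory cytokines 13 of 22 were higher and 1 lower (16 and 1 over the list alone, median log2 fold change 1.95, adjusted p = 9.46e-08, and adjusted p = 0.338 with an estimated correlation). CXCL10, a chemokine, had 0 counts under 5-FU and 57 under AFZC, at least 16.5-fold higher, and TNFRSF9 rose from 0.599 ± 0.263 to 19.2 ± 4.04 CPM (adjusted p = 0.00526). Interferon-stimulated genes rose in 13 of 26 and fell in 0 (15 and 0 over the list alone, median 1.27, or 1.10 with members at 0 counts set to their bound, adjusted p = 4.71e-07, and adjusted p = 0.338 with an estimated correlation). IFITM1 was 32-fold higher by counts (12.2 to 119) and IFIT1 rose from 0.371 ± 0.0115 to 5.09 ± 4.27 CPM (log2 fold change 3.77, or 2.48 without replicate 1 of AFZC). CD74, the invariant chain of class II antigen presentation, was 37.6-fold higher by counts (22.6 to 67.6). Some markers of other cell types rose too: 3 of 7 immune markers, 2 of 5 endothelial and 2 of 4 fibroblast markers. Scarce protein-coding genes rose in SW620 in general, with a median log2 fold change of 0.95 under 1 CPM and 0.66 from 1 to 4 CPM. By counts CD3D was 21.6-fold (8.16 to 80.7) and THY1 24.5-fold (12.7 to 54.2) higher, LYZ was at 6.54 and 28.1 CPM, LUM at 28.9 and 32 CPM (adjusted p = 0.802) and COL1A1 at 23.8 and 23.7 CPM (adjusted p = 1). Calls of CXCL10 and TNFRSF9 were lost without a 5-FU library (adjusted p = 0.0728 without replicate 2 and 0.0852 without replicate 1), and 5 of the 22 NF-kB genes and 6 of the 26 interferon-stimulated genes were higher without replicate 2 of 5-FU. Without replicate 1 of AFZC 8 interferon-stimulated genes were higher and their median was 0.70.

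In all, 2482 genes were higher and 1486 lower in SW620, and 1948 and 458 of these changed at least 2-fold. Other large rises were SRPX2, 60.9-fold by counts (33.8 to 122), ANKRD22, 57.3-fold (24.3 to 178), the keratin KRT6B, 49.2-fold (25.7 to 108), the secreted phospholipase PLA2G2A, 43-fold (19.5 to 118), and PACSIN1, 34.6-fold (17.4 to 80.9). PLA2G2A lost its call without replicate 1 of AFZC (log2 fold change 1.77, adjusted p = 0.349) and in a fit of SW620 alone (adjusted p = 0.0573). In the intestinal differentiation list 6 of 24 rose and 0 fell (7 and 1 over the list alone, adjusted p = 0.0672), and 3 to 10 were higher and 0 to 2 lower over left-out libraries and other settings. PIGR, the polymeric immunoglobulin receptor, had 0 and 249 counts, at least 72.3-fold higher, and GUCA2A, guanylin, was 24.3-fold higher (13 to 51.2). The largest falls besides the histones were PLAC9 (log2 fold change -3.03 ± 0.496) and 3 genes that share sequence with near-identical copies, BOLA2B, RGPD5 and the pseudogene GOLGA2P7 (-4.74, -2.57 and -2.36), whose counts are uncertain. These 3 values came to -1.82, -0.94 and -1.57 without replicate 2, 1 and 2 of 5-FU. BOLA2B and RGPD5 lost their calls without 1 library (adjusted p = 0.273 without replicate 1 of AFZC and 0.268 without replicate 1 of 5-FU), as did BOLA2B without the low-count filter (0.152). Without a composition factor 5141 genes were higher and 445 lower, so that 92% of calls were higher against 62.6%, with the median of all genes shifted by 0.38 on the log2 scale. Without replicate 1 of 5-FU 1531 were higher and 796 lower, without replicate 2 1135 and 448, and without replicate 1 of AFZC 1615 and 859.

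In SW620 fold changes under AFZC were lower for more abundant transcripts. The median log2 fold change of protein-coding genes was 0.95 for 2391 genes under 1 CPM, of which 361 rose and 18 fell, -0.01 between 16 and 64 CPM and -1.09 for the 82 most abundant genes, of which 69 fell and 0 rose. Across 15171 genes, which are not independent replicates, the Spearman correlation of fold change with abundance was -0.454 in SW620 and -0.0122 in HCT116. With this trend taken out, a setting chosen after seeing the data, 2005 genes were higher and 949 lower in SW620.

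**Figure D1:**
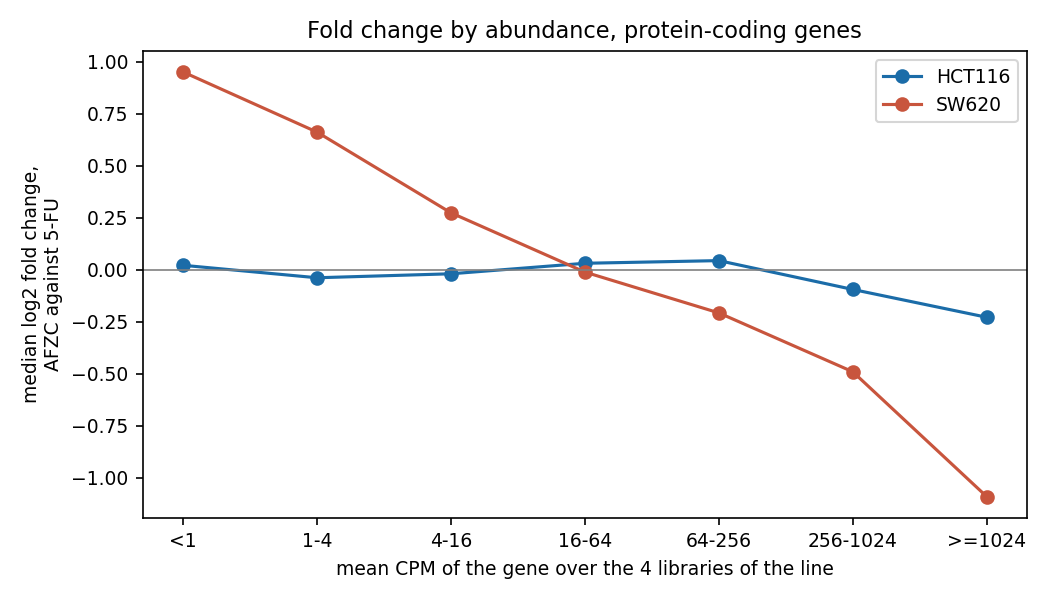
Median log2 fold change of protein-coding genes under AFZC against 5-FU (vertical axis) in 7 classes of mean CPM (horizontal axis), for HCT116 and SW620. In SW620 the medians run from 0.95 in the lowest class to -1.09 in the highest, and in HCT116 from 0.02 to -0.23.

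Several groups of abundant transcripts were lower in SW620, and what remained of each with the trend taken out is given with it. All 38 ribosomal protein mRNAs fell, also over the list alone (median -1.11, adjusted p = 7.67e-38, and adjusted p = 0.265 with an estimated correlation), RPL3 from 3567 ± 382 to 966 ± 458 CPM and RPL10A from 1098 ± 117 to 346 ± 120 CPM. With the trend out, 8 fell and the median was -0.33, and with library sizes only it was -0.73. Of 13 mitochondrially encoded mRNAs 6 fell and 0 rose (9 and 0 over the list alone, median -0.60, adjusted p = 5.89e-06, and adjusted p = 0.338 with an estimated correlation), among them MT-ATP8 and MT-ND4L (-1.38 and -0.95). Without replicate 1 of 5-FU 2 of the 13 were lower. With the trend out, the median of these mRNAs was 0.41 (adjusted p = 0.22), and with library sizes only -0.22. Glycolysis genes fell in 5 of 19 and rose in 0 (8 and 1 over the list alone, median -0.45, adjusted p = 0.000464, and adjusted p = 0.338 with an estimated correlation), led by the transporters SLC2A1 and SLC16A3 (-1.29 and -1.13). Their median was 0.13 with the trend out (adjusted p = 0.965), -0.08 with library sizes only and -0.25 without replicate 2 of AFZC. Over left-out libraries and other settings 1 to 8 glycolysis genes were lower and 0 to 3 higher, and 1 to 9 and 0 to 2 of the mitochondrially encoded mRNAs. The values of SLC2A1, SLC16A3 and MT-ND4L were -0.44, -0.58 and -0.30 with the trend out, and those of the latter 2 -0.75 and -0.57 with library sizes only. SLC2A1 and MT-ND4L then lost their calls (adjusted p = 0.173 and 0.399), and MT-ND4L also with library sizes only (0.0608).

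Cholesterol biosynthesis genes fell in 11 of 24 and rose in 0 in SW620 (12 and 0 over the list alone, median -0.45, adjusted p = 3.63e-07, and adjusted p = 0.364 with an estimated correlation). INSIG1, the sterol sensor, fell from 229 ± 94.5 to 60.7 ± 14.4 CPM. Without replicate 2 of 5-FU 4 of the 24 were lower, and the median was -0.68 without replicate 1 of AFZC and -0.06 with library sizes only. Immediate early and AP-1 genes fell in 12 of 29 and rose in 0 (19 and 0 over the list alone, median -0.63, adjusted p = 1.28e-08, and adjusted p = 0.338 with an estimated correlation), among them PHLDA1 and DUSP4 (-1.35 ± 0.183 and -1.26 ± 0.192). Of the 29 genes 3 were lower without replicate 2 of 5-FU, 7 without either HCT116 5-FU library and 19 without either HCT116 AFZC library. The median was -0.25 with library sizes only and -0.40 with the trend out, and PHLDA1 then stood at -0.59. The integrated stress response had 0 of 29 higher and 6 lower, also over the list alone (median -0.36, adjusted p = 0.000238, and adjusted p = 0.533 with an estimated correlation). DDIT4 and TRIB3 fell most (-2.19 ± 0.49 and -1.35 ± 0.337), and 18 members were lower without replicate 2 of AFZC against 1 without replicate 2 of 5-FU. The list median was -0.05 without replicate 1 of AFZC, -0.91 without replicate 2, 0.01 with library sizes only and -0.22 with the trend out. TRIB3 was at -0.82 and -2.15 without replicate 1 or 2 of AFZC and at -0.81 with the trend out. WNT target genes had 1 of 20 higher, the receptor TNFRSF19 (1.87 ± 0.346), and 6 lower, led by NOTUM, a WNT-inactivating esterase (-1.60 ± 0.188; 2 and 6 over the list alone, adjusted p = 0.0122, and adjusted p = 0.364 with an estimated correlation). Of the WNT genes 2 to 7 were lower and 1 to 4 higher over left-out libraries and other settings. TNFRSF19 was at 1.24 without replicate 1 of AFZC and NOTUM at -0.97 with the trend out. Calls of DDIT4 and TRIB3 were lost without 1 library, with the highest p without replicate 2 of 5-FU (adjusted p = 0.168 and 0.154), and that of DDIT4 without the low-count filter (0.155). With the abundance trend taken out the integrated stress response, TRIB3 and the WNT list did not pass (adjusted p = 0.0719, 0.102 and 0.462), nor did the integrated stress response without replicate 1 of AFZC (0.147) or the WNT list without replicate 2 (0.145).

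Ferroptosis genes did not move as groups in SW620. Drivers had 3 of 22 higher and 1 lower (4 and 1 over the list alone, adjusted p = 0.848) and suppressors 3 of 23 higher and 3 lower (3 and 6 over the list alone, adjusted p = 0.32). Over left-out libraries and other settings 1 to 6 drivers were higher, 1 to 8 suppressors higher and 0 to 6 lower. The lipoxygenases ALOX15, with 3 and 27 counts, a ratio of 7.84 (2.41 to 40.4), and ALOXE3 (log2 fold change 1.79 ± 0.447, or 1.10 without replicate 2 of AFZC) were among those higher. From the suppressor list PROM2 was higher (1.91 ± 0.417), as was CD44, a hyaluronan receptor that promotes iron uptake. CD44 rose from 7.65 ± 3.66 to 30.9 ± 8.43 CPM (adjusted p = 0.000751). GPX4 was at 257 ± 22.4 and 189 ± 1.06 CPM (adjusted p = 0.0812), ACSL4 at 284 ± 14.7 and 208 ± 52.2 CPM (adjusted p = 0.0978) and SLC7A11 at 170 ± 15.3 and 81 ± 52.8 CPM (adjusted p = 0.135). HMOX1 rose from 5.3 ± 1.22 to 10.4 ± 2.3 CPM (log2 fold change 0.98 ± 0.253, adjusted p = 0.0185). NRF2 targets fell in 11 of 28 and rose in 2 (12 and 2 over the list alone, median -0.43, adjusted p = 2.98e-07, and adjusted p = 0.19 with an estimated correlation), led by the transporter ABCC3 and PIR (-1.35 ± 0.186 and -1.33 ± 0.156), with 5 to 12 lower and 0 to 2 higher over those settings and a median of -0.05 with library sizes only and -0.23 with the trend out. In the metallothionein and zinc list 3 of 10 rose, MT1F and MT1L among them (2.46 ± 0.396 and 2.58 ± 0.509), and 0 fell (3 and 1 over the list alone, adjusted p = 0.0909, and 3 to 6 and 0 to 2 over those settings), with MT2A at 103 ± 62.3 and 160 ± 83.8 CPM (adjusted p = 0.408). Without 1 library the calls of ALOX15 and HMOX1 (replicate 1 of 5-FU, adjusted p = 0.102 and 0.137) and of ALOXE3 and PROM2 (replicate 2 of 5-FU, 0.144 and 0.0847) were lost. With the abundance trend taken out ALOX15 and HMOX1 did not pass (adjusted p = 0.0519 and 0.0605), nor did ALOX15 and PROM2 in a fit of SW620 alone (0.0592 and 0.0765).

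**Figure D2:**
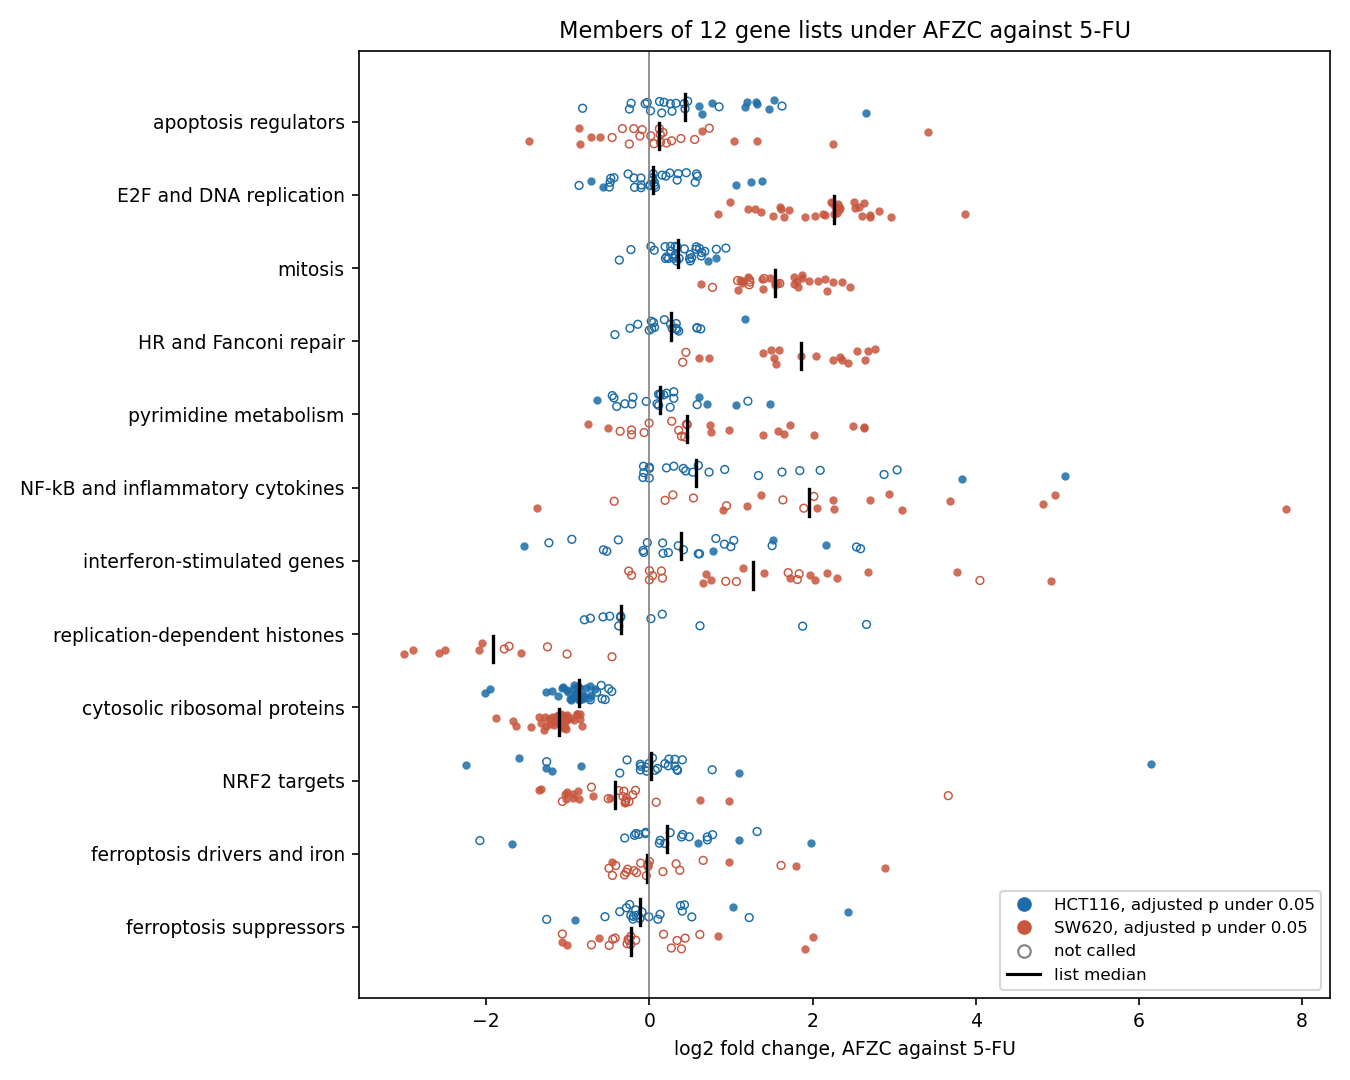
Log2 fold change under AFZC against 5-FU (horizontal axis) of each measured member of 12 gene lists (vertical axis) in HCT116 and SW620; filled points have an adjusted p under 0.05, open points do not, and black bars are list medians. The replication genes have a median of 0.04 in HCT116 and 2.26 in SW620, and the ribosomal proteins -0.86 and -1.11.

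The interaction term tested whether the 2 lines responded differently. The effect of AFZC was more positive in SW620 than in HCT116 for 1207 genes and more negative for 884. Replication genes had a more positive effect in SW620 in 32 of 33 members (33 over the list alone, median difference 2.10, adjusted p = 7.82e-63, and adjusted p = 0.0106 with an estimated correlation). The difference was -2.62 ± 0.295 for CDKN1A (adjusted p = 0.000299), -2.46 ± 0.406 for MDM2 (adjusted p = 0.00453) and 2.04 ± 0.373 for TYMS (adjusted p = 0.0052), while for GPX4, HMOX1, SLC7A11, ACSL4 and MT2A it did not pass the test (adjusted p of 0.625, 0.89, 0.915, 0.473 and 0.999). Among the largest differences were genes silent in 1 line under 5-FU that AFZC brought to low counts there. In SW620 these were CD40, DPYSL5, HLA-DRA, OLFML2B and RET, at least 37.4-, 19.7-, 18.3-, 8.71- and 9.29-fold higher, and in HCT116 HS3ST6, CBS and KIAA1755, at least 47.3-, 21.9- and 7.62-fold higher, with KRT17 and SYT8 beside them. The bounds pool AFZC libraries that differed. In replicates 1 and 2 CD40 had 103 and 26 counts, DPYSL5 45 and 23 and HLA-DRA 49 and 14. In HCT116 HS3ST6 had 116 and 33, CBS 41 and 28 and KIAA1755 14 and 10. CBS has a near-identical copy, CBSL, with 0 counts under 5-FU and 22 and 10 under AFZC in HCT116, so its counts and bound are uncertain. HS3ST6 and KIAA1755 lost the call without replicate 1 of HCT116 5-FU (adjusted p = 0.0894 and 0.0787) and KRT17 without replicate 1 of SW620 AFZC (0.0619). Without a composition factor 2455 differences were positive and 430 negative, 85.1% positive against 57.7%, with a shift of 0.35 in the median, and without replicate 1 of HCT116 5-FU 478 and 279.

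**Figure D3:**
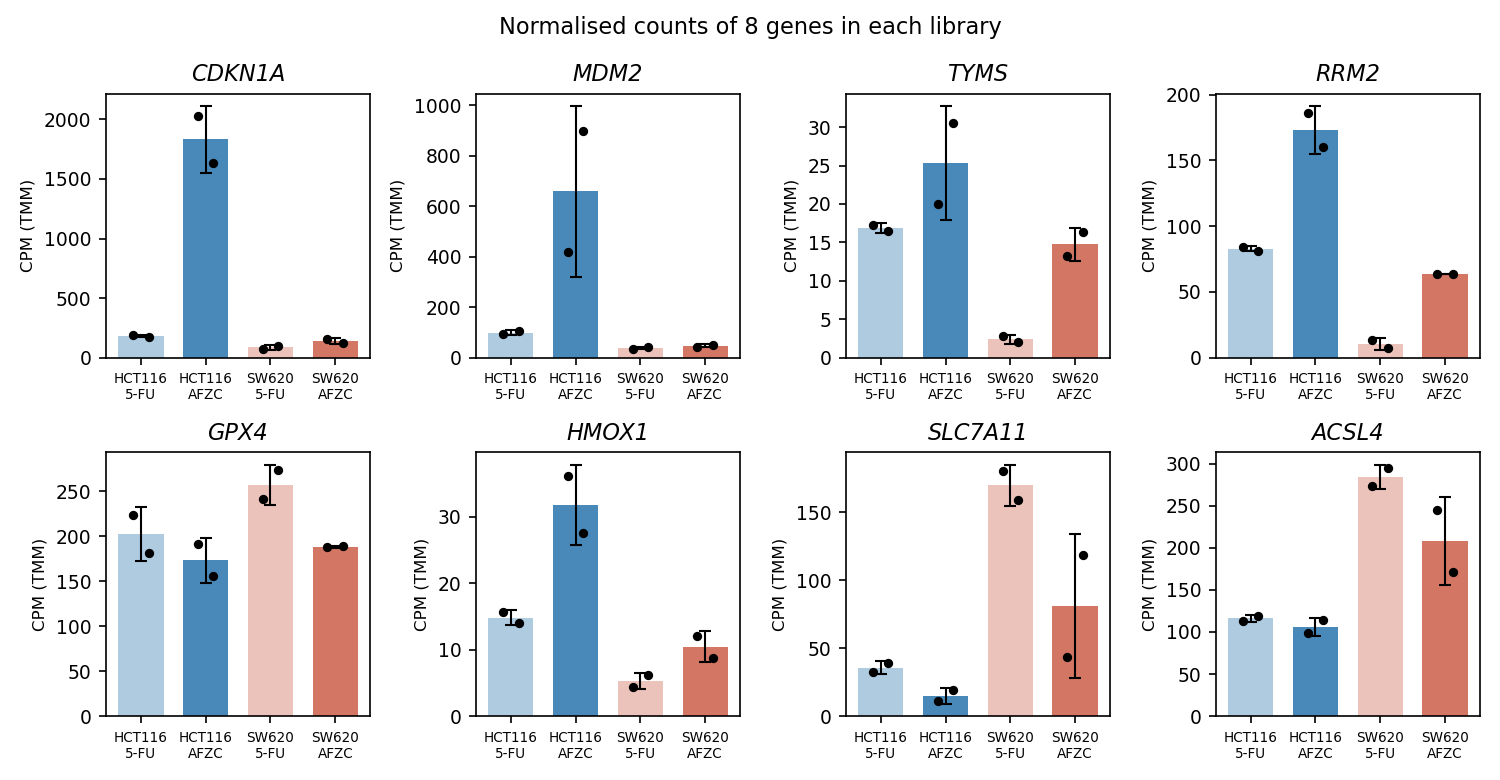
Normalised counts (CPM with TMM factors, vertical axes from 0) of 8 genes in the 4 groups; bars are means, error bars SD, and points the 2 libraries of each group. CDKN1A reaches 1832 CPM in HCT116 under AFZC against 140 in SW620, and TYMS in SW620 rises from 2.39 to 14.8 CPM.

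Some genes moved the same way in both lines. There were 257 genes higher in both, where independent lists would share 146 (odds ratio 2.07, Fisher's exact test across genes, p = 1.01e-20), and 263 lower in both against 55.6 (odds ratio 7.75, p = 8.05e-111). In opposite directions, 82 were higher in HCT116 and lower in SW620, against 87.2 for independent lists (Fisher's exact test across genes, p = 0.606). The reverse held for 53 genes, against 92.9 (Fisher's exact test across genes, p = 2.07e-06). Fisher's test treats genes as independent, while some, such as ribosomal protein mRNAs, vary together. Its p-values here do not measure the spread between libraries. HMOX1, ALOXE3 and PROM2 were higher in both lines, and RPL3 and RPL10A lower in both. Over 21378 genes, which are not independent replicates, log2 fold changes correlated with Pearson's r = 0.214 and Spearman's rho = 0.185. Without replicate 1 of HCT116 5-FU 48 genes were higher and 34 lower in both, and with the abundance trend taken out 241 and 175.

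Under 5-FU itself the lines differed in most genes, with 5675 higher and 6030 lower in SW620. TXNIP, a thioredoxin inhibitor, GJB1, ROBO1, TOX3 and the WNT receptor FZD10 had 0 counts in HCT116 and were at least 134000-, 6360-, 5670-, 5440- and 3650-fold higher in SW620. SLC1A3, PCDH7, COL12A1, MEF2C and AMOTL1 had 0 counts in SW620 and were at least 4630-, 3160-, 2550-, 2190- and 1720-fold lower. Replication genes were lower in SW620 in 30 of 33 and higher in 1, also over the list alone (median -1.56, adjusted p = 1.82e-10, and adjusted p = 0.365 with an estimated correlation). Intestinal differentiation genes were higher in 17 of 24 and lower in 4, also over the list alone (adjusted p = 1.23e-07, and adjusted p = 0.727 with an estimated correlation). Without a composition factor 35.6% of calls were higher in SW620 against 48.5%, with a shift of -0.30 in the median.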

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

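The genes and lists given here with values were singled out because the effect of AFZC differed between the 2 lines, by the interaction term of edgeR for genes and by camera on that term for lists, with an adjusted p under 0.05. Of the 3 patterns weighed, the second is shared by both lines and the third was picked by counts, without a test of the difference. Of the tests below, those of reads from the other line (genes without counts and share supplied), of the gain of genomic DNA, of genes as abundant as the ribosomal list and of the abundance trend were chosen only after the result was seen. Of 34 gene lists 20 differed, and 1 of them, the replication list, also did so with an estimated correlation. Of 105 named genes compared, 57 differed. Some of these genes, such as CD40, HLA-DRA and CBS, were named because their difference was among the largest, so they could not fail. Many others were named for a large effect in 1 line. The 57 of 105 is therefore no estimate for genes in general. Over all 21378 genes tested, 9.78% differed. Values in the next 2 paragraphs are log2 effects in SW620 minus HCT116.

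Lists with a higher median effect in SW620 were E2F and DNA replication (2.10), homologous recombination and Fanconi repair (1.67), mitosis (1.07), interferon-stimulated genes (0.68), pyrimidine metabolism (0.63) and immune cell markers (2.52). Lists with a lower one were replication-dependent histones (-1.71), mitochondrially encoded mRNAs (-0.87), immediate early and AP-1 genes (-0.81), WNT targets (-0.79), the integrated stress response (-0.74), NRF2 targets (-0.51), heat shock (-0.42), cholesterol biosynthesis (-0.36), apoptosis regulators (-0.35), ribosome biogenesis (-0.31), the nuclear-encoded respiratory chain (-0.23), cytosolic ribosomal proteins (-0.22), intestinal differentiation (-0.16) and glycolysis (-0.14). Apart from the replication list, the adjusted p of these lists with an estimated correlation was between 0.0826 and 0.732. The differences of the ribosomal protein, glycolysis, intestinal differentiation, WNT, interferon, respiratory chain, ribosome biogenesis and immune marker lists were each lost without 1 library (adjusted p up to 0.398, 0.0935, 0.264, 0.068, 0.208, 0.263, 0.113 and 0.107). The median for intestinal differentiation turned without replicate 1 of HCT116 AFZC, replicate 2 of SW620 5-FU or replicate 2 of SW620 AFZC (0.07, 0.11 and 0.13). With the abundance trend taken out those of NRF2 targets, mitochondrially encoded mRNAs, WNT targets, glycolysis, the respiratory chain, ribosome biogenesis and immune markers were lost (adjusted p = 0.218, 0.094, 0.218, 0.927, 0.603, 0.218 and 0.0612). The medians of ribosomal proteins and glycolysis then turned to 0.35 (adjusted p = 0.0027) and 0.09. Those of NRF2 targets, mitochondrially encoded mRNAs, WNT targets, the respiratory chain, ribosome biogenesis, heat shock, cholesterol biosynthesis and intestinal differentiation came to -0.28, -0.29, -0.43, 0.00, -0.17, -0.19, -0.19 and -0.30. With library sizes only, also chosen after the data were seen, ribosomal proteins, glycolysis, the respiratory chain, ribosome biogenesis and immune markers lost the call (adjusted p = 0.241, 0.157, 0.39, 0.115 and 0.156). The medians of the first 4 then turned to 0.13, 0.21, 0.12 and 0.04, those of intestinal differentiation, apoptosis regulators and cholesterol biosynthesis to 0.21, 0.01 and 0.00. Those of heat shock, NRF2 targets, the integrated stress response, AP-1 genes, WNT targets and mitochondrially encoded mRNAs came to -0.06, -0.16, -0.39, -0.44, -0.44 and -0.52, and of pyrimidine metabolism and interferon-stimulated genes to 0.98 and 1.03. Over the left-out libraries the median ran from -1.28 to -0.29 for AP-1 genes, -1.08 to -0.49 for WNT targets, -1.38 to -0.38 for the integrated stress response, 0.31 to 0.81 for pyrimidine metabolism and 0.76 to 1.73 for mitosis. It ran from -0.54 to -0.21 for cholesterol biosynthesis, -0.37 to -0.17 for apoptosis regulators, -0.42 to -0.03 for ribosomal proteins, -0.25 to -0.09 for glycolysis and -0.45 to 0.13 for intestinal differentiation. For the respiratory chain it came to -0.35 and -0.11 without replicate 1 or 2 of HCT116 5-FU, for heat shock to -0.66 without replicate 2 of SW620 AFZC and for ribosome biogenesis to -0.11 without replicate 1.

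Genes with a higher effect in SW620 were SPARC (6.32), CUBN (3.81), RRM2 (1.57), E2F8 (2.49), AKR1C1 (1.31), BST2 (3.83), TYMS (2.04), CCNE2 (2.51), AURKB (1.86), RAD54L (2.43), EME1 (2.42), MT1F (2.65), CD44 (2.20), IFIT1 (3.54), CASP10 (2.56) and TNFRSF19 (2.83). Genes with a lower effect were TP53I3 (-3.62), CDKN1A (-2.62), RRM2B (-1.70), SLC30A1 (-1.84), AIFM2 (-1.64), FOSL1 (-2.53), FAS (-1.34), TNFRSF10A (-2.13), EPHB3 (-1.45), MDM2 (-2.46), HIST2H2BE (-2.10), HIST1H2AC (-1.94), GOLGA2P7 (-2.41), BBC3 (-2.23), INSIG1 (-1.60), SLC2A1 (-1.55), SLC16A3 (-1.39), MT-ATP8 (-1.45), MT-ND4L (-1.38), DUSP4 (-1.39) and NOTUM (-1.25). For genes at few or 0 counts in a group the fitted difference depends on the prior count and is no bound: HRNR (-6.37), KRT17 (-7.62), SYT8 (-7.50), MUC2 (-5.57), MUC13 (-4.38), SRPX2 (3.80), ANKRD22 (5.85), CD74 (5.80), PACSIN1 (4.85), IFITM1 (6.16), PIGR (6.92), HIST1H2BG (-5.67), CD40 (9.39), DPYSL5 (8.40), HLA-DRA (7.77), OLFML2B (7.52), RET (7.31), HS3ST6 (-9.12), CBS (-8.29) and KIAA1755 (-6.83).

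The first pattern weighed was replication genes rising in SW620 and not in HCT116. Under 5-FU 30 of these 33 genes were already lower in SW620 (median -1.56), and this gap enters the difference with the opposite sign. By list means the gap under 5-FU was -1.62 and the difference of effects 2.06, so on average the rise was larger than the gap. SW620 against HCT116 under AFZC was not tested. Without untreated cells, a stronger effect of 5-FU in SW620 cannot be told from an effect of AFZC. Scaling between libraries was set against a difference between the lines. Median-of-ratios factors and library sizes only shifted the differences of all genes by a median of 0.00417 and 0.354, both upward. The median difference closest to 0 over 3 scalings was 2.10 for these genes, which argues against the choice among these scalings as the source. Leaving out any 1 library left at least 2.06, and taking out the abundance trend 2.12. The lines differ in many ways, and no test here separates these.

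The second pattern was the lower level of ribosomal protein mRNAs in both lines. Against genes matched for length, GC content and abundance the list lay at -0.77 in HCT116 and -0.56 in SW620, with 0 of 10000 random matched lists as low. The random lists drew each gene independently, while ribosomal protein mRNAs vary together (estimated correlation of 0.882 in HCT116 and 0.879 in SW620). The 0 of 10000 is therefore no p-value for the list, and camera with an estimated correlation gave adjusted p = 0.854 and 0.265. The matched genes were also less abundant than the list (mean log2 CPM of 9.14 against 10.1 in SW620). Against 47 genes at least as abundant as the list median the list lay at -0.91 in HCT116 and -0.18 in SW620, and with the trend taken out its median was -0.67 and -0.33. The median closest to 0 over 3 scalings was -0.84 and -0.73, which argues against the choice among these scalings. In HCT116 library sizes only shifted the fold changes of all genes by a median of just 0.0208, and in SW620 by 0.375. In HCT116 the sizes of the list medians argue against length, GC content, abundance and the choice among these scalings as the source. In SW620 the fall may be part of a general fall of abundant transcripts, whose cause was not tested.

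The third pattern was genes that went from 0 counts in both 5-FU libraries to at least 10 in each AFZC library, 53 in HCT116 (GGT6 among them) and 88 in SW620 (PIGR, CD40 and HLA-DRA among them), with more counts in replicate 1 of AFZC for 43 of the 53 and 53 of the 88, 0 genes in common and 3 and 1 in the opposite direction. After thinning all libraries to 31991561 counts the lowest AFZC library still held 201 and 1861 more detected genes than the highest 5-FU library. This compares all detected genes, not the 53 and 88 alone. In HCT116 the 5-FU libraries held 26404 and 27346 genes after thinning, a wider gap than 201, so thinning decides little there. In SW620 both AFZC libraries had lower totals (31991561 and 33426910) than both 5-FU libraries (33520117 and 40590291), so depth does not account for the newly detected genes there. Of genes abundant in the other line and silent under 5-FU, 83.3% (10 of 12) had no count in HCT116 AFZC libraries and 43.8% (7 of 16, 95% interval 19.8 to 70.1) in SW620, so that traces of HCT116 reads in SW620 are not excluded, yet the highest share seen supplies 0.55% and 3.09% of the reads over these genes. Genomic DNA, read from 381 olfactory receptor genes, stood at 0.252 and 0.106 of the median level of these genes, over the bound of 0.1 set beforehand, with AFZC and 5-FU libraries overlapping. The largest gain of that signal came to 13% and 1.84% of the level, so genomic DNA may add to these genes but did not supply most of them, and no biological explanation was tested.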

How the results depend on the processing

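Of the settings here, loess offsets and library sizes only for gene lists were chosen after seeing the data. Leaving out 1 library leaves its group with 1, which is then assumed to vary like the other groups. In HCT116, genes higher ranged from 216 to 1509 over the left-out libraries and genes lower from 89 to 1215, with 1306 lower without the low-count filter. In SW620, genes higher ranged from 1135 to 2703 and were 5141 with library sizes only, and genes lower ranged from 448 to 1741 and were 445 with library sizes only and 949 with loess offsets. For the difference between lines, genes more positive in SW620 ranged from 478 to 1521, with 2455 for library sizes only and 1848 without the filter, and genes more negative from 279 to 1112, with 430 for library sizes only. Genes higher in both lines ranged from 48 to 369, with 517 for library sizes only and 489 without the filter, and genes lower in both from 34 to 332, with 142 for library sizes only and 175 with loess offsets.

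The gene lists called higher in HCT116 were 5, against 1 with an estimated correlation, 1 with fry and 8 with loess offsets, and those called lower 2, against 0 with an estimated correlation, 0 with fry and 1 to 4 over the left-out libraries. In SW620 9 were called higher, against 2 with an estimated correlation, and 13 lower, against 1 with an estimated correlation, 5 with fry and 5 with loess offsets. For the difference between lines 6 were more positive, against 1 with an estimated correlation, and 15 more negative, against 1 with an estimated correlation, 3 with fry and 8 with loess offsets. The direction of the value for MT2A turned in SW620 without replicate 2 of AFZC (-0.02734, with 1.441 as the highest value, without replicate 2 of 5-FU), and that of camera for the mitosis list in HCT116, whose median was 0.00279, without replicate 2 of AFZC (adjusted p = 0.417, with 3.15e-18 as the lowest, without replicate 1 of AFZC). Camera's direction also turned with loess offsets for glycolysis (adjusted p = 0.965) and mitochondrially encoded mRNAs (adjusted p = 0.22) in SW620 and for the difference of ribosomal protein mRNAs between lines (adjusted p = 0.0027). Apart from the effect of fewer libraries, the cause of these moves was not tested.

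Results under each setting were sorted by direction and call alone, whatever the size of the value. Weaker means that the call was lost, stronger that one was gained, and reversed that the direction turned. Among planned settings 483 list results were the same, 116 weaker and 1 reversed. Results of named genes were the same in 1955 cases, weaker in 133, stronger in 9 and reversed in 1. Among added settings 73 list results were the same, 24 weaker and 3 reversed, and 126 gene results were the same and 6 weaker. A value could move and still count as the same, as for AKR1B10 in HCT116 (6.14, or 11.49 without replicate 1 of 5-FU). DESeq2 called 1543 higher and 1172 lower in HCT116 and 2655 and 1714 in SW620. Replicate numbers do not pair libraries by the data (correlations of deviations of 0.0209 and -0.0254), and with the number as a block 1137 and 692 genes were called in HCT116 and 2271 and 1384 in SW620. With the block ATF3, DKK1 and BOLA2B lost their calls (adjusted p = 0.0734, 0.0509 and 0.0581), as did the difference between lines of the intestinal differentiation list (0.155) and the fibroblast markers in SW620 (0.0669). Fits on the 4 libraries of 1 line give no value for the difference between lines. Depth limits genes under about 0.1 CPM in a single library, since 3 counts in 1 library correspond to 0.0795 to 0.103 CPM. The bounds on fold changes take 3 counts over both libraries of a group, which is a lower floor.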

Other observations

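The hypothesis on CDKN1A below was chosen only after the result was seen. Several further lists were counted without naming most members. In SW620 the heat shock list had 1 of 23 genes higher and 5 lower (adjusted p = 0.0175, and adjusted p = 0.404 with an estimated correlation). The nuclear-encoded respiratory chain had 0 of 30 higher and 3 lower (adjusted p = 0.000666, and adjusted p = 0.505 with an estimated correlation), and ribosome biogenesis 2 of 30 higher and 4 lower (adjusted p = 0.026, and adjusted p = 0.619 with an estimated correlation). Nuclear and snoRNA host long RNAs had 0 of 8 higher and 3 lower (adjusted p = 0.00228, and adjusted p = 0.338 with an estimated correlation). Without 1 library the call was lost for heat shock (adjusted p up to 0.0978) and ribosome biogenesis (0.409). With the trend taken out heat shock, the respiratory chain, ribosome biogenesis and nuclear long RNAs did not pass (adjusted p = 0.874, 0.131, 0.534 and 0.0722), and with library sizes only the first 3 did not (0.0711, 0.0794 and 0.302). Markers of foreign cells passed in SW620 as lists: fibroblast 2 of 4 higher (adjusted p = 0.0346, and adjusted p = 0.461 with an estimated correlation), immune 3 of 7 (adjusted p = 0.00449, and adjusted p = 0.2 with an estimated correlation) and endothelial 2 of 5 (adjusted p = 0.035, and adjusted p = 0.364 with an estimated correlation). Each of these 3 was lost without 1 library (adjusted p up to 0.264, 0.0541 and 0.242), fibroblast and endothelial markers with the trend out (0.0602 and 0.0719) and endothelial markers with library sizes only (0.13). Levels under 5-FU and AFZC were, for PDGFRB, 2.20 and 9.53 CPM, for CSF1R 0.883 and 6.92 and for VWF 3.11 and 12.1. The lists for copper handling (0 and 0 of 22), peroxide detoxification (3 and 3 of 26), the unfolded protein response (1 and 0 of 22), fatty acid synthesis (2 and 5 of 17), hypoxia (2 and 2 of 25), autophagy (4 and 6 of 30) and epithelial junctions (3 and 4 of 21) did not pass there (adjusted p of 0.336, 0.869, 0.318, 0.166, 0.0652, 0.336 and 0.539).

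In HCT116 the unfolded protein response had 0 of 22 genes higher and 1 lower, HSP90B1 (adjusted p = 0.043, and adjusted p = 0.886 with an estimated correlation), with the call lost without replicate 1 of 5-FU or 2 of AFZC (adjusted p = 0.0692 and 0.227). The other lists did not pass in HCT116, with genes higher and lower of 4 and 0 for heat shock, 1 and 1 for copper handling, 3 and 1 for peroxide detoxification, 0 and 2 for fatty acid synthesis, 1 and 0 for hypoxia, 0 and 2 for the respiratory chain. They were 5 and 1 for ribosome biogenesis, 2 and 0 for autophagy, 6 and 2 for epithelial junctions, 1 and 0 for fibroblast, 0 and 0 for immune and 0 and 1 for endothelial markers, and 0 and 1 for nuclear long RNAs. HSPA4L, a heat shock protein of the HSP110 family, rose from 39.2 ± 1.46 to 140 ± 2.18 CPM (adjusted p = 4.42e-05), and KDR, the VEGF receptor 2, had 105 counts under 5-FU and 9 under AFZC.

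With CDKN1A about 10-fold higher in HCT116, repression of replication and mitosis genes could be expected as a hypothesis. The lowest list medians over the 8 left-out libraries were -0.0451 for the replication list and 0.00279 for the mitosis list. Repression beyond the level under 5-FU was thus not seen, and a weak one is not excluded. Untreated cells were not analysed, so repression present under both agents cannot be judged.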
